A study of Mus musculus with 8 samples.

How the data were processed

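MicroRNA (miRNA) levels were measured in bone marrow neutrophils of male mice aged 8 weeks on the BKS background. Per the labels' protocols, marrow from 3 mice was combined into each pool, neutrophils were isolated with a magnetic kit, and small RNA was purified with a kit built on mouse Argonaute 2 (Ago2), the protein that holds mature miRNAs. Cyanine-3 label was added to 100 ng of RNA, and each pool was hybridised to 1 array of the Agilent SurePrint G3 mouse miRNA platform, per the labels' protocols. Of the 8 pools, 4 came from Lepr db/db mice (labelled diabetic, pools 1 to 4) and 4 from db/+ mice (labelled non-diabetic, pools 5 to 8).

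The deposited scanner tables hold intensity values on a linear scale, 1 row per spot, from Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, a spatial background fit had been subtracted within each array, outlier spots had been marked, and no surrogate values had been used for dim spots, so that processed intensities can be negative. The scanner tables of db/db pool 1 keep 3 significant digits, as a spreadsheet would save them. Per the file headers, probe positions refer to the mouse build mm9. The deposited value table of the whole series was compared with the scanner tables and equalled the total signal per miRNA of Feature Extraction, with a largest difference of 0 on each array. These values are therefore linear, uncentred and not scaled between arrays, with 0.1 where a miRNA was not detected. The median of each of its columns was 0.1.

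From the background-subtracted intensity, spots marked as outliers were left out and the spots of a probe were averaged. Each array was divided by its 75th percentile over the probes detected on all arrays, values were floored at 0.0126 of that percentile (the median over arrays of the lowest scaled signal of a detected probe, log2 = -6.30), and log2 was taken. A probe counted as detected on an array where over 0.5 of its spots were well above background. A miRNA was represented by its brightest probe over the 8 arrays and tested where any of its probes was detected on at least 4 arrays. Of 1881 miRNAs on the array (4415 probes, 56430 spots), 425 were tested. Among 331 tested miRNAs with 2 or more detected probes, 29 had probes of opposite sign.

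The comparison of db/db with db/+ used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 pools, with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests are two-sided. Each log2 fold change is db/db minus db/+, with its moderated standard error (SE). A miRNA not well above background on any pool of a group has only a bound there. The bound sets the mean of the brighter group against the dim group's mean of the higher of each array's lowest detected signal and the probe's own signal. Values of single arrays were compared by exact permutation over the 70 arrangements of the 8 pools, where the smallest possible p is 0.0286.

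The question, the 14 lists, the tests and most of the other settings were fixed before the data were examined. The lists were miR-129 family, granulocyte, myeloid precursor, erythroid, lymphoid, monocyte and macrophage, stromal and endothelial, NF-kB-linked, diabetes-linked, miR-17 clusters, let-7 family, miR-15/16 family, imprinted Dlk1-Dio3, and doubtful annotation. The last holds GC-rich entries and entries that overlap ribosomal or transfer RNA. Lists were tested with limma's camera at a preset correlation of 0.01, over lists with at least 3 tested members. The estimated correlation and fry, which tests whether the members of a list move one way on balance, were run beside it. Some miRNAs stand on more than 1 list, such as miR-126a-5p, miR-144-3p, miR-146a-5p and miR-155-5p. The miRNAs named are up to 12 per direction with the largest change past the threshold, filled to 5 by smallest p where fewer passed, all tested members of the miR-129 family, miR-223-3p, miR-142a-3p, and up to 3 members of each list with the smallest p. This gave 42 miRNAs. A miRNA named outside this rule is said to be so.

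The fit was tested on simulated data with the means and spreads of the 425 tested miRNAs in db/db against db/+. It called 65.5% of miRNAs changed by 1 on the log2 scale and 91.8% of those changed by 2, and 4.84% of its calls were unchanged miRNAs. The camera step found all 20 simulated lists shifted by 1 and none of 20 unshifted lists. The simulated miRNAs varied independently and were not floored, while the estimated correlation within the real lists ran up to 0.88. The simulation therefore gives no error rate for correlated lists or for miRNAs on the floor.

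The 8 arrays lie on 1 slide, read in 1 scan. The db/db pools occupy slide row 1 and the db/+ pools slide row 2, so that row and genotype cannot be told apart, and the planned block for slide or scan could not be run. No pool number is shared between the groups. Other settings covered the signal (Feature Extraction's total signal, normexp with an offset of 50, the deposited value table), the scaling (none, all probes, the 90th percentile, quantile, the median), the detection filter, the floor, the rule for several probes, the variance model, array weights and each pool left out. The labelling spike-ins as scale, the slide column as a block, the mean of the doubtful annotation list as a covariate, leaving out db/db pool 4 with db/+ pool 8, and leaving out each pool with the tested miRNAs kept the same were chosen after seeing the data.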

Results

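The series asked which miRNAs differ in neutrophils of diabetic mice. Mice with 2 copies of the db allele of the leptin receptor gene Lepr become obese and diabetic, and db/+ mice of the same strain do not. Neutrophils, the most abundant phagocytes of the marrow, were taken from 4 pools of db/db and 4 pools of db/+ marrow, each pool holding 3 mice, and Ago2-bound small RNA was profiled on 1 array per pool. The number of arrays limits the precision. No spot was saturated by the scanner's flag (0 spots).

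The db/db arrays carried less miRNA signal before scaling. The number of miRNAs detected was 382.5 ± 26.9 (SD, n = 4) on the db/db arrays and 473.75 ± 46.5 (SD, n = 4) on the db/+ arrays (exact permutation p = 0.0286, the smallest possible). On the log2 scale the 75th percentile of signal was 9.82 ± 0.55 (SD, n = 4) in db/db and 10.94 ± 0.57 (SD, n = 4) in db/+. This is a 2.17-fold lower level, which did not pass the test (exact permutation p = 0.0571). The spike-in RNAs added at labelling, dmr_285 and dmr_31a, differed by 0.14 and 0.12 on the log2 scale, higher in db/db, within the spread between pools (exact permutation p = 0.371 and 0.571). The spike-ins dmr_3 and dmr_6 differed by 0.0058 and 0.012 (exact permutation p = 0.8 and 0.629). All fold changes below are after scaling to each array's 75th percentile unless said otherwise. Without scaling, the median log2 fold change of the 425 tested miRNAs was -1.05 and 265 miRNAs were called lower and 0 higher.

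**Figure D1:**
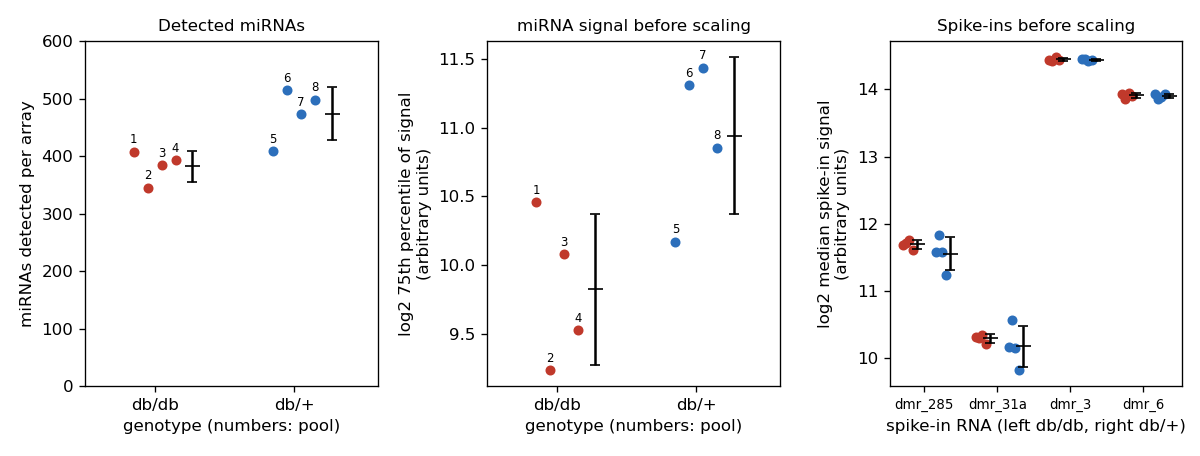
Detected miRNAs (left), log2 75th percentile of miRNA signal (middle) and log2 spike-in signal (right), in arbitrary scanner units, for the 4 db/db (red) and 4 db/+ (blue) arrays, with mean ± SD in black and pool numbers beside the points. The db/db arrays hold 345 to 408 detected miRNAs and the db/+ arrays up to 515, while the spike-ins of both groups lie close together.

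Members of the miR-129 family were lower in db/db neutrophils. miR-129-5p was not well above background on any of the 4 db/db pools and was detected on all 4 db/+ pools. It was thus at least 3.12-fold lower in db/db. The limma fit, which sets db/db at the floor, gave 3.99-fold (limma, adjusted p = 0.000134). That p belongs to the larger, floored difference and does not test the bound. The raw signal of miR-129-5p was 7.28 ± 3.88 (SD, n = 4) in db/db and 109.5 ± 48.6 (SD, n = 4) in db/+. All 4 db/db values of miR-129-5p were set to the floor (SD 0), so its p uses no measured spread in db/db. It was 1 of 6 miRNAs detected on all db/+ and no db/db pools, and the others had limma adjusted p of 0.61 or more. miR-129-2-3p was detected on all 8 pools and was 2.95-fold lower in db/db, with a log2 fold change of -1.56 (SE 0.25, limma, adjusted p = 0.0402). Its raw signal was 19.7 ± 2.97 (SD, n = 4) in db/db and 133.4 ± 56.1 (SD, n = 4) in db/+, and the pools of the 2 groups did not overlap for either miRNA. The probe of miR-129-2-3p maps to mm9 chromosome 2, positions 94081582 to 94081598, and the files give no position for the probes of miR-129-5p. These were the only 2 of the 425 tested miRNAs past the threshold in the limma fit.

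The other tested members did not pass over all miRNAs. miR-129b-5p had a log2 fold change of -0.58 (SE 0.17, limma, adjusted p = 0.128) and miR-129b-3p one of -0.16 (SE 0.16, limma, adjusted p = 0.625). miR-129-1-3p, not tested and named outside the naming rule, was not well above background on any array. As a group the 4 tested members had a median log2 fold change of -1.07 (camera, adjusted p = 4.72e-05; adjusted p = 0.249 with an estimated correlation), and 3 passed when adjusted over the list alone. The published study of these samples chose this family on the same samples, so the list is not independent evidence of its direction. The probes of miR-129-2-3p and miR-129-1-3p share most of their sequence, and the 2 of miR-129-1-3p had mean raw signals of 3.59 and 14.3 in db/+. With the same miRNAs tested, miR-129-5p passed whichever single pool was left out (limma, adjusted p at most 0.00212). Leaving out a db/db pool removes only a floored value of miR-129-5p, so those fits are a weak check. With the detection filter applied anew, the call of miR-129-2-3p ended when db/db pool 1, 3 or 4 was left out (limma, adjusted p = 0.0656, 0.194 and 0.111) or db/+ pool 5, 6 or 8 (0.0686, 0.168 and 0.11), at log2 fold changes of -1.43 to -1.67. It also ended with the mean over probes, where its log2 fold change was -0.78 (limma, adjusted p = 0.0779) and its other probe was detected on 0 pools. It ended with quantile normalization, the sum over probes, no detection filter or detection on all 8 arrays as well, at -1.45 to -1.61. With the total signal and with the deposited values it passed in the fit as such and did not relative to the median of all miRNAs (adjusted p = 0.0758 and 0.445). With normexp background correction neither member passed. Their log2 fold changes relative to the median of all miRNAs were then -0.48 for each. The offset of 50 is larger than the mean raw db/db signals of miR-129-5p (7.28) and miR-129-2-3p (19.7). Such an offset shrinks the fold changes of dim probes, so this setting cannot decide on either.

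**Figure D2:**
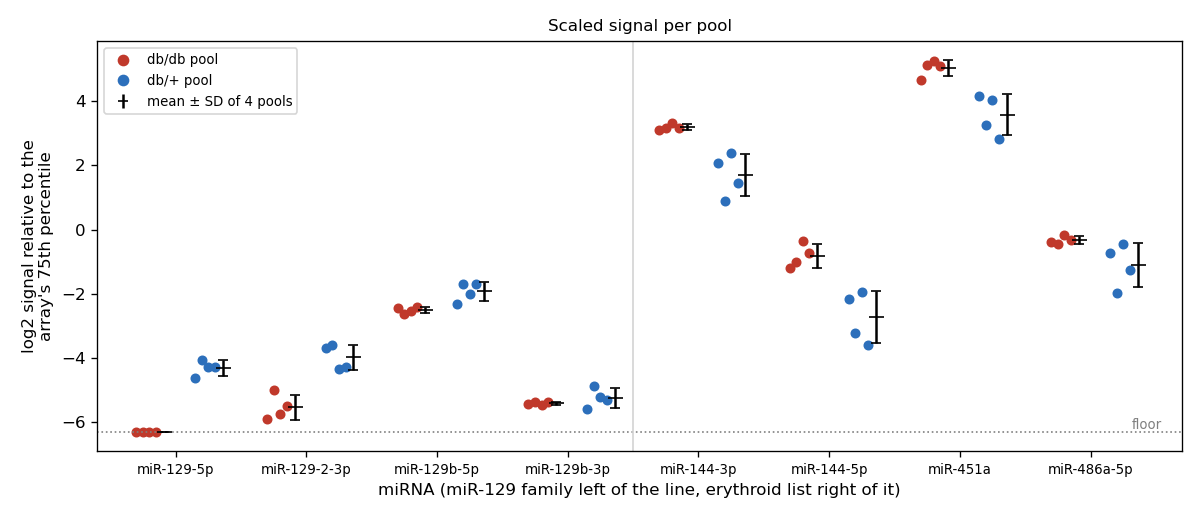
Log2 signal relative to each array's 75th percentile for the tested members of the miR-129 family (left of the line) and of the erythroid list (right of it), 1 point per pool (red db/db, blue db/+), with mean ± SD in black. The dotted line is the floor, on which all 4 db/db pools lie for miR-129-5p, and the db/db pools of miR-144-3p, miR-144-5p and miR-451a lie above all db/+ pools.

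No miRNA was called higher in db/db by the main limma fit (0 at the adjusted threshold; 51 higher and 20 lower at an unadjusted p under 0.05). With the slide column as a block, a fit chosen after seeing the data, 3 were called higher, namely miR-144-3p, miR-144-5p and miR-1949, the last named outside the naming rule. The smallest p among higher miRNAs belonged to the erythroid list, miRNAs abundant in red cell precursors. The log2 fold change was 1.49 (SE 0.30) for miR-144-3p and 1.90 (SE 0.38) for miR-144-5p, both with a limma adjusted p of 0.0686 (0.0378 and 0.0367 with the block for slide column). For miR-451a it was 1.46 (SE 0.30, limma, adjusted p = 0.0737). In each case all 4 db/db pools lay above all 4 db/+ pools. Their probes lie within 1 short stretch of mm9 chromosome 11, from 77886513 to 77886709. The fourth tested member, miR-486a-5p of another locus, named outside the naming rule after its value was seen, had a log2 fold change of 0.76 (SE 0.30, limma, adjusted p = 0.232). The list shifted up as a group, with a median of 1.48 (camera, adjusted p = 0.000502; adjusted p = 0.376 with an estimated correlation). None of its 4 members passed over all miRNAs (0), and all 4 passed when adjusted over the list alone. Before scaling, the raw signal of miR-451a was 30758 ± 9247 (SD, n = 4) in db/db and 25953 ± 13984 (SD, n = 4) in db/+, so that the difference appears relative to the other miRNAs of the array. Without scaling the log2 fold changes of miR-451a, miR-144-3p and miR-144-5p were 0.34, 0.37 and 0.79, with 1 SE of 0.42 for all miRNAs, and none passed (limma, adjusted p = 0.454, 0.41 and 0.0885). Relative to the median of all miRNAs, miR-144-5p then stood at 1.85 and passed (limma, adjusted p = 0.0056), as it did with spike-in scaling (adjusted p = 0.0071). The test without scaling kept the common SE of 0.42, so it does not use the spread of miR-144-5p itself.

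The remaining miRNAs filled in by smallest p did not pass in the main fit either. On the higher side they were miR-130a-3p (log2 fold change 0.64, SE 0.15) and miR-106b-5p (0.84, SE 0.20), both with a limma adjusted p of 0.103. On the lower side they were miR-28a-3p (log2 fold change -0.79, SE 0.16, limma, adjusted p = 0.0686), miR-669n (-0.84, SE 0.18, limma, adjusted p = 0.081) and miR-466h-5p (-0.55, SE 0.14, limma, adjusted p = 0.122). miR-130a-3p, miR-106b-5p and miR-669n passed with trend and robust (limma, adjusted p = 0.0495 each), miR-669n with normexp relative to all miRNAs (adjusted p = 0.0448) and miR-28a-3p with the doubtful annotation mean as a covariate (adjusted p = 0.0456).

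The granulocyte list, miRNAs abundant in neutrophils and their maturation, shifted up as a group, with 8 of 10 tested members positive and a median log2 fold change of 0.44 (camera, adjusted p = 0.00564; adjusted p = 0.376 with an estimated correlation). None passed over all miRNAs (0), and 2 passed when adjusted over the list alone. These were miR-223-3p, a regulator of granulocyte maturation, at 1.17 (SE 0.31, limma, adjusted p = 0.122) and miR-142a-3p at 0.87 (SE 0.25, limma, adjusted p = 0.128). miR-23a-3p stood at 0.43. The raw signal of miR-223-3p was 202184 ± 9134 (SD, n = 4) in db/db and 195505 ± 13239 (SD, n = 4) in db/+, and that of miR-142a-3p was 136583 ± 22738 (SD, n = 4) and 160740 ± 14838 (SD, n = 4). Unscaled log2 fold changes were 0.05 and -0.24. Quantile normalization gave 0 for both, as it must for a probe of the same rank on every array, so this 0 is no evidence on their level. The median of the list was 0.05 relative to all miRNAs with normexp (camera, adjusted p = 0.0873) and 0.03 with quantile normalization (camera, adjusted p = 0.459).

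The miR-15/16 family, which targets cell cycle and survival genes, also shifted up, with all 6 tested members positive and a median of 0.49 (camera, adjusted p = 0.00564; adjusted p = 0.376 with an estimated correlation). None passed over all miRNAs (0) and 4 passed when adjusted over the list alone. miR-15b-5p stood at 0.90 (SE 0.22), miR-16-5p at 0.60 (SE 0.19) and miR-15a-5p at 0.45 (SE 0.14). Quantile normalization gave -0.15 for miR-16-5p. The median of the list was then 0.13 (camera, adjusted p = 0.308), and with normexp it was 0.18 relative to all miRNAs (camera, adjusted p = 0.0889). Within groups, log2 raw signal rose by 0.63 for miR-15b-5p, 0.55 for miR-16-5p and 0.83 for miR-15a-5p per log2 unit of the scaling percentile. The tested miRNAs had a median of 0.90, and miR-195a-5p, named outside the naming rule, had 1.20. These slopes were chosen after the results were seen. A slope below 1 raises scaled values where the scale is lower, as on the db/db arrays. The fold changes of miR-15b-5p and miR-16-5p may thus partly reflect that lower scale. The stromal and endothelial list shifted up with a median of 0.38 over 6 members (camera, adjusted p = 0.0244; adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone, 2 of them passed, miR-126a-5p of vascular endothelium at 0.80 and miR-199b-5p at 0.42. In the same list miR-126a-3p, named outside the naming rule, stood at -0.04. miR-199a-3p stood at 0.47. The median was 0.13 relative to all miRNAs with normexp (camera, adjusted p = 0.166) and 0.31 with quantile normalization (camera, adjusted p = 0.102). The miR-17 clusters, which promote proliferation, had 14 of 17 members positive and a median of 0.19 (camera, adjusted p = 0.0397; adjusted p = 0.772 with an estimated correlation). Adjusted over the list alone, 1 passed, miR-106b-5p, while miR-19b-3p stood at 0.69 and miR-17-5p at 0.50. With normexp background correction the median of this list was -0.07 relative to all miRNAs, and with quantile normalization it was 0.02 (camera, adjusted p = 0.245). The let-7 family with miR-98, miRNAs of differentiated cells, shifted down, with 7 of 9 members negative and a median of -0.17 (camera, adjusted p = 0.0397; adjusted p = 0.772 with an estimated correlation). None passed when adjusted over the list alone (0). let-7b-5p stood at -0.40, miR-98-5p at -0.48 and let-7c-5p at -0.32. The median of the list was -0.54 relative to all miRNAs with normexp (camera, adjusted p = 4.56e-06) and -0.35 with quantile normalization (camera, adjusted p = 0.00388). The within-group slopes were 1.28 for let-7b-5p, 1.46 for miR-98-5p and 1.25 for let-7c-5p, against a median of 0.90 over the tested miRNAs. A slope above 1 lowers scaled values where the scale is lower. The shift of this list may therefore partly reflect the lower scale of the db/db arrays. A difference of genotype in this family stays open.

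By fry, 4 of the 14 lists passed, namely the miR-129 family (adjusted p = 0.00185) and the granulocyte, erythroid and miR-15/16 lists (adjusted p = 0.0287 each). These 4 also passed camera whichever single pool was left out. With normexp background correction 2 lists passed camera, erythroid and let-7, and without scaling 2 did, miR-129 and erythroid. The stromal and endothelial call ended without db/db pool 3 (adjusted p = 0.0931) or db/+ pool 6 or 8 (0.0765 and 0.102). That of the miR-17 clusters ended without db/db pool 1 or 3 (adjusted p = 0.14 and 0.235) or db/+ pool 6 or 8 (0.0999 and 0.438). That of the let-7 family ended without db/db pool 2 or 4 (adjusted p = 0.165 and 0.149) or db/+ pool 5, 6 or 7 (0.117, 0.0999 and 0.168). With the slide column as a block neither the miR-17 clusters (camera, adjusted p = 0.0614) nor the let-7 family (0.0734) passed. The call of the miR-17 clusters also ended with the total signal (camera, adjusted p = 0.0995), no detection filter (0.104), detection on all 8 arrays (0.105), the mean (0.0581) or sum (0.0699) over probes, the covariate (0.401) and without pools 4 and 8 (0.0698). That of let-7 also ended with the total signal (camera, adjusted p = 0.0599) and array weights (0.146), and the stromal and endothelial one with detection on all 8 arrays (0.0656) and the covariate (0.112). Over the 37 other settings the miR-17 clusters passed in 11, let-7 in 16 and the stromal and endothelial list in 19. Each pool left out enters both with the detection filter applied anew and with the same miRNAs tested. The settings are therefore not independent checks.

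**Figure D3:**
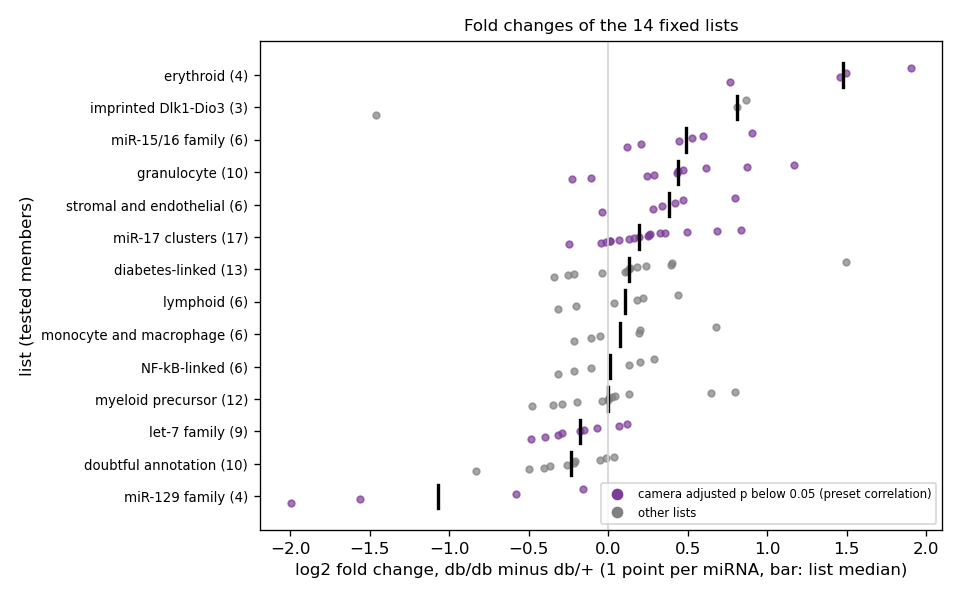
Log2 fold changes (db/db minus db/+) of the tested members of each fixed list, 1 point per miRNA, with the list's median as a black bar and the number of members in brackets. Purple lists passed camera with the preset correlation, and none passed with an estimated one; the erythroid median lies at 1.48 and the miR-129 family's at -1.07.

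The other 7 lists did not pass camera. Lymphoid miRNAs had a median of 0.11 over 6 members (camera, adjusted p = 0.904), with miR-150-5p at 0.44, miR-181c-5p at 0.22 and miR-155-5p at -0.31. Monocyte and macrophage miRNAs had a median of 0.07 over 6 members (camera, adjusted p = 0.928), with miR-511-3p at 0.68, miR-146b-5p at 0.20 and miR-146a-5p at -0.21. With normexp background correction the medians of both these lists were below 0, at -0.16 and -0.25 relative to all miRNAs. Myeloid precursor miRNAs had 6 of 12 members on either side of 0 and a median of 0.00077 (camera, adjusted p = 0.904). In this list miR-130a-3p and miR-126a-5p passed when adjusted over the list alone, and miR-10b-5p stood at -0.48. NF-kB-linked miRNAs had a median of 0.0098 over 6 members (camera, adjusted p = 0.965), with miR-21a-5p at 0.29. In the myeloid precursor list the median and mean were above 0 and camera's direction was down, and in the NF-kB-linked list the median was above 0 and the mean (-0.0026) and camera's direction below. Diabetes-linked miRNAs had a median of 0.13 over 13 members (camera, adjusted p = 0.434). Only miR-144-3p passed when adjusted over that list alone, and miR-29b-3p stood at 0.40 and miR-320-3p at -0.34.

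Of the 27 miRNAs listed for the imprinted Dlk1-Dio3 cluster, 3 were tested (camera, adjusted p = 0.965). They stood at 0.87 for miR-376b-3p, 0.81 for miR-376a-3p and -1.46 for miR-494-3p, with a median of 0.81 and a mean of 0.07. With 1 pool left out, miR-376b-3p ran from 0.45 to 1.27, miR-376a-3p from 0.48 to 1.19 and the median from 0.45 to 1.19. miR-494-3p passed relative to the median of all miRNAs without scaling (-1.52, limma, adjusted p = 0.0372) and with spike-in scaling (adjusted p = 0.0441). Without scaling the SE was 0.42 for all miRNAs, so that test does not use the spread of miR-494-3p itself. The doubtful annotation list, kept as a sign of background RNA, had a median of -0.24 over 10 members (camera, adjusted p = 0.141; adjusted p = 0.87 with an estimated correlation), with miR-5100 at -0.83, miR-6366 at -0.50 and miR-1894-3p at -0.41. With 1 pool left out these ran from -1.42 to -0.45, from -0.87 to -0.18 and from -0.56 to -0.27. Its mean per array ran from -3.39 to -2.04 in db/db and from -3.58 to -1.88 in db/+, a difference between the groups within the spread between pools (exact permutation p = 0.6). This list passed camera without db/db pool 4 (adjusted p = 0.00757) or without db/+ pool 7 (adjusted p = 0.0115), and its median ran from -0.56 to -0.046 with 1 pool left out. It also passed camera with the slide column as a block (adjusted p = 0.0367), with array weights (adjusted p = 0.0167), with no detection filter (adjusted p = 5.75e-05) and without pools 4 and 8 (adjusted p = 0.0323). All these passes are with the preset correlation, and in the main fit, where the estimated correlation of its members was 0.88, the list did not pass with it (camera, adjusted p = 0.87 with an estimated correlation).

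Over all tested miRNAs, 47 (11.1%) had pools that did not overlap between the groups, against 2.86% on average over all arrangements of the pools. The share was not counted for the other splits, and miRNAs vary together, so whether it exceeds chance was not tested. Without db/db pool 4 and db/+ pool 8, the arrays with the highest doubtful annotation mean in their groups, limma called 0 miRNAs. miR-129-2-3p stood at -1.68 (limma, adjusted p = 0.18), and miR-129-5p left the tested set because it was detected on 3 pools.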

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

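Within groups of 4 pools, 97 sets of values were examined for a pool far from the others, and 3 stood apart by Dixon's criterion for 4 values, where chance alone gives about 1 in 20. let-7b-5p in db/db pool 2 stood at 2.79 (log2, relative to the 75th percentile), and the other 3 db/db pools lay between 3.23 and 3.25. miR-17-5p in db/db pool 3 stood at -0.15, and the other 3 lay between -0.48 and -0.44. miR-181c-5p in db/+ pool 5 stood at 0.87, and the other 3 lay between 1.04 and 1.08. The 3 values lie in 3 different pools.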

How the results depend on the processing

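The scale by labelling spike-ins, the block for slide column, the doubtful annotation mean as a covariate, the fits that kept the tested miRNAs the same while a pool was left out, and the fit without db/db pool 4 and db/+ pool 8 were chosen after seeing the data. No paired analysis was possible because the labels give no number that pairs db/db with db/+ pools: the groups share no pool number and every pool carries the same replicate number. The block for slide column sets 1 db/db against 1 db/+ array in each column, and so pairs array positions, not mice. The block for slide or scan was not run, since all arrays share 1 slide and 1 scan. Values below are log2 fold changes, given relative to the median of all miRNAs where a setting moved that median by over 0.1. The median stood at -0.11 with Feature Extraction's total signal, 0.35 with normexp, -1.12 with the deposited values, -1.05 without scaling, -0.17 with the percentile over all probes and -1.18 with spike-in scaling. The cause of a change was not tested unless it is named.

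The main count of 2 miRNAs, both lower, became 265 without scaling and 311 with spike-in scaling, all lower (0 higher), because the whole distribution shifts. It became 1 with quantile normalization, with no detection filter (more miRNAs tested), with the mean and with the sum over probes, in each case miR-129-5p. It became 0 among miRNAs detected on all 8 arrays, which leaves miR-129-5p out by construction, and 0 without pools 4 and 8. With normexp it was 3 higher (miR-144-3p, miR-144-5p and miR-451a, none past the threshold relative to the median of all miRNAs) and 0 lower. It rose to 8 with trend and robust (5 higher, miR-106b-5p, miR-130a-3p, miR-144-3p, miR-144-5p and miR-451a; 3 lower, with miR-669n), 4 with array weights (2 higher), 5 with the slide column as a block (3 higher, miR-144-3p, miR-144-5p and miR-1949) and 7 with the doubtful annotation mean as a covariate (4 higher, 3 lower; beside the miR-129 members miR-144-3p, miR-144-5p, miR-451a, miR-28a-3p and miR-680, the last named outside the naming rule). Leaving out 1 pool gave 0 to 5 miRNAs, 0 to 2 higher and 0 to 3 lower. It was 0 without db/+ pool 5, 6 or 8, where miR-129-5p left the tested set, as it also did without db/+ pool 7. With the same miRNAs tested it was 1, miR-129-5p, without pool 5, 6 or 8 and 5 without db/+ pool 7. It was 1 without db/db pool 1, 3 or 4. miR-129-5p passed under 28 of 29 settings that tested it and miR-129-2-3p under 14 of 35, with limma adjusted p from 1.79e-05 to 0.216 and from 0.00479 to 0.445. Both were lower in db/db under each of these. Fits with a pool left out enter both with the filter applied anew, where the miRNA was still tested, and with the same miRNAs kept. The settings are therefore not independent checks. These tallies test relative to the median of all miRNAs where a setting moved it by over 0.1, while the counts of miRNAs above are from the fits as such; with the total signal and the deposited values miR-129-2-3p passes only in the latter.

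The main count of 7 lists became 2 with normexp (erythroid and let-7), and 2 with the deposited values, without scaling or with spike-in scaling (miR-129 and erythroid). It was 3 with quantile normalization (miR-129, erythroid and let-7). It was 4 with the 75th or 90th percentile over all probes, with the median as scale and with fry (miR-129, granulocyte, erythroid and miR-15/16), and 0 with an estimated correlation. Leaving out 1 pool gave 4 to 7 lists. Apart from pools left out singly, 760 of 795 values of named miRNAs and 205 of 294 list values kept their direction and their side of the threshold, while 6 and 29 changed sign.

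With normexp, miR-129b-3p stood at 0.12, miR-146b-5p at -0.16, miR-181c-5p at -0.15 and miR-21a-5p at -0.10, and the list medians at -0.23 for myeloid precursor, -0.16 for lymphoid, -0.25 for monocyte and macrophage, -0.28 for NF-kB-linked, -0.25 for diabetes-linked and -0.066 for the miR-17 clusters. With quantile normalization, miR-16-5p stood at -0.15 and miR-21a-5p at -0.21, and the medians at -0.047 for myeloid precursor, -0.018 for monocyte and macrophage, -0.18 for NF-kB-linked and -0.011 for diabetes-linked. With no detection filter the myeloid precursor list passed camera (adjusted p = 0.0106) at a median of 0, with the preset correlation (in the main fit, adjusted p = 0.977 with an estimated correlation). Its median was -0.078 with the total signal and with the deposited values, -0.054 without scaling, -0.053 with spike-in scaling, -0.019 and -0.073 with the 75th and 90th percentile over all probes, -0.0089 with the median as scale, -0.0028 among miRNAs detected on all 8 arrays, -0.0082 with a floor of 0.25 of the main one, -0.024 and -0.037 with the mean and the sum over probes, -0.035 with the covariate and -0.0062 without pools 4 and 8. The NF-kB-linked median was -0.044 without scaling and with spike-in scaling, and -0.010 and -0.064 with the 75th and 90th percentile over all probes. The monocyte and macrophage median was -0.0024 with the 90th percentile. The doubtful annotation median was 0.035 with its own mean as covariate, by construction. Leaving out 1 pool moved the myeloid precursor median from -0.13 to 0.070 and the NF-kB-linked one from -0.029 to 0.047. It moved by over 1.5 times also the medians of the lymphoid (0.049 to 0.18), monocyte and macrophage (0.0066 to 0.16), diabetes-linked (0.076 to 0.17) and miR-17 (0.13 to 0.29) lists, and miR-129b-3p (-0.27 to -0.033), miR-146a-5p (-0.34 to -0.11), miR-146b-5p (0.11 to 0.33), miR-155-5p (-0.46 to -0.18) and miR-21a-5p (0.18 to 0.34). The miR-129 family's median ran from -1.16 to -0.50, where miR-129-5p left the tested set without a db/+ pool. With the same miRNAs tested it ran from -1.16 to -0.97. Signal over background limits miR-129-5p, which lies on the floor in db/db. Its fold is a bound, and its p in the main fit uses the floor as its db/db level.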

Other observations

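The tests on splits that keep the slide columns, name families, control features, spike-ins, the unscaled median, miR-486a-5p, the lymphoid, monocyte and stromal lists and signal slopes were chosen after the results were seen, and miR-93-5p and miR-25-3p are named outside the naming rule. Detection was lopsided between the groups. Of 1881 miRNAs, 558 were detected on any pool. Of these, 24.4% were detected on db/+ pools only, 1 miRNA on db/db pools only, and 421 on pools of both groups. Detection depends on raw signal, which was lower on the db/db arrays.

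Families formed by name, with 4 or more tested members, were tested with camera as an addition, 10 in all. None passed (0 at the adjusted threshold, 0 with an estimated correlation). The smallest adjusted p was 0.0592, for the 4 tested 5p members of the miR-467 family, which lay between -0.55 and -0.22 on the log2 scale. The 5 members of the miR-467 family on the 3p side were all positive (0.12 to 0.48, camera, adjusted p = 0.38), and so were all 9 of miR-669 on the 3p side (0.14 to 0.61, camera, adjusted p = 0.201). These families belong to 1 large cluster of repeated miRNA genes. Within the miR-106b cluster on mm9 chromosome 5, miR-106b-5p stood at 0.84, miR-93-5p at 0.25 and miR-25-3p at 0.16, and none passed (limma, adjusted p = 0.103, 0.355 and 0.495).

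The control features hur_1, hur_2, hur_4 and hur_6 were lower on the db/db arrays by log2 differences of -1.99, -2.01, -2.20 and -1.16, with an exact permutation p of 0.0857 for each and an adjusted p of 0.2 over the 21 control features. The sources used here do not say which RNA they match. The negative control features NC2_00092197 and NC2_00106057 were higher on each db/db array than on any db/+ array (0.80 against 0.15 and 1.65 against 0.77 on the log2 scale; exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.2), at signals below those of the detected miRNA probes. The rank correlation of log2 fold change with the GC content of the probe was -0.34, and 17 of the 35 splits of the pools into 4 and 4 gave one as far from 0, the real one included. The test of this correlation was written down before its result was seen and was later taken out of the patterns weighed below, to keep their number small.

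Chance could not be excluded for the number of miRNAs called. The real split gave 2 miRNAs, and 2 of the 35 splits of the 8 pools into 4 and 4 gave as many, the real one included. The other was pools 1, 2, 3 and 7 against 4, 5, 6 and 8, with 40 miRNAs, which points to a structure of the samples other than genotype. It sets both arrays of slide column 3 (pools 3 and 7) against both of column 4 (pools 4 and 8). The 8 splits that keep 1 pool of each column on either side are too few for a share under 0.05; there the real split gave 2 miRNAs (5 with the column as a block) and the highest other 0 (0 with the block). The mean of the doubtful annotation list was -2.998, -3.38, -3.39 and -3.58 in pools 1, 2, 3 and 7 and -2.04, -2.36, -2.87 and -1.88 in pools 4, 5, 6 and 8. Nor could chance be excluded for the number of lists. The real split gave 7, the highest other split 9, and 6 of the 35 splits gave as many or more. Among the 8 splits that keep the columns, the real one gave 7 lists (6 with the block) and the highest other 6 (4 with the block).

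The total miRNA signal was lower on the db/db arrays. Weaker labelling or hybridisation would lower the labelling spike-ins as well, and the bound set for it was a log2 difference of -0.56. They were higher in db/db by 0.13 (interval from exact permutation -0.29 to 0.53), which argues against it. The median unscaled log2 fold change of all tested miRNAs was -1.05. A smaller amount of small RNA in the labelled material may account for it, and so may less miRNA per cell in db/db mice. These cannot be told apart, since no value separates the amount loaded from the amount in the cells and each genotype has its own slide row.

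miR-223-3p and miR-142a-3p had the 2 highest fold changes of the granulocyte list after scaling. A candidate explanation is compression of bright signals, so that the raw value stays flat while the scale factor changes. Within groups, log2 raw signal rose by 0.12 for miR-223-3p and 0.32 for miR-142a-3p per unit of the log2 75th percentile, against a median of 0.90 over the 425 tested miRNAs. This is what compression would give, so that their scaled fold changes may reflect the lower scale of the db/db arrays. A genuine difference of genotype in these miRNAs stays open.

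miR-144-3p, miR-144-5p and miR-451a had fold changes of 1.46 to 1.90 on the log2 scale without passing in the main fit, and miR-144-3p and miR-144-5p passed with the slide column as a block (limma, adjusted p = 0.0378 and 0.0367). The 40 miRNAs nearest in level had 95th percentiles of at most 0.69, below the lower interval end of each of the 3 (0.77 or more). This cannot decide on compression, since the 3 were picked as the higher miRNAs with the smallest p. Their within-group slopes, taken as for miR-223-3p, were 0.88, 0.91 and 0.72, against a median of 0.90 over the tested miRNAs. With a pool left out they stayed at 0.46 or more, and that of miR-142a-3p at 0.37 or less. These slopes argue against compression as strong as in miR-223-3p and miR-142a-3p, and a weaker one stays open. A lower share of neutrophils, if all other cell types rose alike, would raise the markers of each. The lymphoid, the monocyte and macrophage and the stromal and endothelial medians were 0.11, 0.07 and 0.38 (member SD 0.28, 0.32 and 0.27) against 1.48 for the erythroid list, although the stromal and endothelial list passed camera. These values cannot exclude carry-over of a single cell type, which would raise only its own markers. More RNA of red cell precursors in the db/db pools is a hypothesis that the fourth member goes with, as miR-486a-5p stood at 0.76 (95% interval 0.07 to 1.46, adjusted p = 0.232); the neutrophil isolation kit is meant to leave such cells out. A change of these miRNAs within db/db neutrophils was not tested and stays open.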
